A study of Mus musculus with 18 samples.

How the data were processed

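RNA from the cerebral cortex, hippocampus and hypothalamus of mice lacking the taste receptor subunit T1R3 (gene Tas1r3) and of wild-type C57BL/6J mice was measured on Illumina bead arrays, 1 array per sample. The labels give 3 regions and 2 genotypes, with 3 animals in each of the 6 groups and 18 animals in all. The animals were 4 to 5 months old. The knockout line had been crossed to C57BL/6J for at least 4 generations, per the series' design text. The groups and the replicate numbers were taken from the sample titles. The same numbers, 1 to 3, occur in every group, and no source says that a number marks an animal, a litter or a day.

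The deposited table of intensity values holds 1 bead signal per probe and array on a linear scale, not normalized between arrays and with no value below 0. Each deposited intensity is followed by a detection p-value, which in Illumina's readout compares a probe with the negative control beads of its array. The deposited detection p-values were multiples of about 0.00125. GenomeStudio 2011.1 was used, per the submitters' processing notes, and the background treatment is not given in the sources used here. The authors' processed values are a z score per probe: each deposited score equalled the log signal of its array, minus the array's mean and divided by its SD, to within 5.0e-10. Probes were named from the platform annotation of the array. Of 25697 probes, 23978 had 1 gene symbol, 0 had several and 1719 had none. Symbols were updated through the RefSeq gene table of the assembly GRCm38.p6, which held 14547 of the 14554 named probes tested. No build is named for the arrays, so that table was used for names, chromosomes and the order of genes, and no coordinates are given. Slide and scan date are not given in the sources used here, so arrays could not be compared by batch.

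The signals were background-corrected with the detection p-values, quantile-normalized and put on the log2 scale with neqc in limma 3.58.1 (R 4.3.3), with an offset of 16. Probes detected at p under 0.05 on at least 3 arrays were tested, which left 15476 probes of 10517 named genes. One limma fit held a mean for each of the 6 groups over the 18 arrays, with 12 residual degrees of freedom, and moderated statistics came from eBayes. The contrasts were knockout against wild type in each region, the mean of the 3 region contrasts, a moderated F test of whether the knockout effect differed between regions, and the regions within wild type. P-values were adjusted by Benjamini-Hochberg over the probes tested, with a threshold of 0.05. All adjusted p-values for single probes in the text are from limma. Log2 fold changes are knockout minus wild type and are given ± SE. A probe not detected on any array of a group has only a bound there. Its ratio is given as "at least N-fold", the brighter group's mean against, per array, the higher of the probe's own value and the lowest value among detected probes. The number of arrays limits the precision.

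The 33 gene lists of pathways, cell types and brain regions, the tests, the thresholds and the rule for naming genes were fixed before the data were examined. One list served to check the sex of the animals and 32 were tested. Each list was tested with camera in limma, with 1 probe per gene (the probe of highest mean level) and a preset correlation between genes of 0.01. Adjustment was over the lists of a region. Camera with an estimated correlation and fry were run as alternatives. Reactome pathways of 10 to 300 measured genes, from fgsea 1.28.0, were tested with camera in the same way, 741 in each region. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

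Genes were named by a fixed rule. It took Tas1r3 on every array. In each region it took the 10 largest rises and the 10 largest falls among genes past the threshold whose knockout and wild-type arrays did not overlap. For the average over regions it took 5 of each, and for the test between regions the 5 smallest p-values. It also took the 10 smallest p-values among genes past the threshold in all 3 regions. From each list it took up to 4 members past the threshold, or up to 2 of smallest p as values where none passed. For each region's markers it took the 3 of highest level in wild type. Genes named outside the rule are said to have been chosen after their values were seen.

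The fit was tested on simulated data in which probes were shifted by known amounts. The simulated noise was normal and independent between probes and arrays, with the same SD for a probe on every array. The shares below therefore do not cover arrays of uneven quality or deviations shared between arrays or probes. At a log2 change of 1, 84% of the 100 shifted probes were recovered in cortex, 86% in hippocampus, 84% in hypothalamus, 98% for the average over regions and 73% for the test between regions. At a log2 change of 0.5 the shares were 45%, 35%, 40%, 77% and 12%. Of the probes called, 3.01% had not been shifted in cortex, 2.42% in hippocampus, 6.06% in hypothalamus, 5.41% for the average and 6.59% for the test between regions.

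The alternatives fixed in advance were no background correction, the deposited z scores, no filter on detection, detection on all 18 arrays, 1 probe per gene, a fit to the 6 arrays of a region, the replicate number as a block, the animal as a random block, array quality weights, a threshold of 0.10, and leaving out each array in turn. The deposited values and the z scores had been planned as separate alternatives and were run once, since they are the same numbers.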

Results

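The series profiled gene expression in 3 brain regions of mice without T1R3, the subunit shared by the sweet and umami taste receptors, and of wild-type mice. Cortex, hippocampus and hypothalamus were each represented by 3 knockout and 3 wild-type arrays. Mean signal per array ranged from 788 to 1388 intensity units, and 52.1% to 58.1% of the probes were detected. The Y-linked genes Uty, Kdm5d and Eif2s3y were detected on 18 of 18 arrays, and each of the 2 Xist probes on 1. The first principal component, with 57.5% of the variance, and the second, with 17.5%, separated the regions. The third, with 6.36%, separated the genotypes in every region: the 9 knockout arrays lay between 5.61 and 27.5 and the 9 wild-type arrays between -15.6 and -6.85.

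Tas1r3 itself lay at the background in both genotypes. Its probe was detected on 1 of 18 arrays, the wild-type cortex array 2. Mean signal was 122 ± 9.63 (SD, n = 3) in knockout and 132 ± 19.8 in wild-type cortex. In hippocampus it was 119 ± 4.07 and 125 ± 7.86, and in hypothalamus 137 ± 23.2 and 122 ± 11.7. The probe therefore gives no check of the genotype labels, and its place relative to the deleted part of the gene is not given in the sources used here. The partner subunits Tas1r1 and Tas1r2 were detected on 0 of 18 arrays, with signals of 89.3 ± 12.2 and 93.6 ± 8.82 over the 18 arrays. Of the 18 taste receptor and taste signalling genes, 4 were measured. Gnb1, a G protein beta subunit used well beyond taste cells, rose in cortex (log2 fold change 0.70 ± 0.15, adjusted p = 0.0207) and in hypothalamus (0.86 ± 0.15, adjusted p = 0.00523). It also lies near Tas1r3 on distal chromosome 4.

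The wild-type regions differed widely and carried their known markers. Pmch, the precursor of melanin-concentrating hormone, stood at 15.20 ± 0.15 (SD, n = 3) on the log2 scale in hypothalamus, against 5.54 ± 0.02 in cortex and 5.90 ± 0.21 in hippocampus. Hap1 and Sparc were also highest in hypothalamus, at 14.64 ± 0.12 and 14.70 ± 0.06. Fibcd1, a marker of hippocampal area CA1, was at 12.74 ± 0.06 in hippocampus and 9.24 ± 0.18 in hypothalamus. Crym was at 13.04 ± 0.08 in hippocampus and 11.60 ± 0.14 in cortex. Dkk3 was level between cortex, 14.19 ± 0.14, and hippocampus, 14.15 ± 0.04. Mef2c, a transcription factor of excitatory neurons, was at 13.97 ± 0.05 in cortex, 12.70 ± 0.30 in hippocampus and 10.21 ± 0.06 in hypothalamus. Egr1 and Lmo4 were likewise highest in cortex, at 14.69 ± 0.07 and 14.36 ± 0.06. Of the measured markers, 19 of 26 for cortex, 20 of 23 for hippocampus and 27 of 28 for hypothalamus were highest in their own region and past the threshold. In all, 8466 of 15476 probes differed between the regions by limma's F test. Cortex and hippocampus differed at 2872 probes, cortex and hypothalamus at 7668, and hippocampus and hypothalamus at 6500.

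Across the regions, the knockout differed from wild type in a common set of genes. Fcer1g, the signalling chain that activating Fc receptors share on microglia and other myeloid cells, was detected on 9 of 9 wild-type arrays and on 0 of 9 knockout arrays, at least 11.8-fold lower (adjusted p = 1.5e-15). Gramd4, a GRAM domain protein, behaved in the same way, at least 9.67-fold lower (adjusted p = 1.5e-14). B3galt6, an enzyme that builds the linker of proteoglycan chains, fell by 2.60 ± 0.09 on the log2 scale, and Clstn1, the neuronal membrane protein calsyntenin 1, fell by 1.67 ± 0.07. Masp2, a protease of the complement lectin pathway, was detected on 9 knockout and 0 wild-type arrays, at least 3.33-fold higher (adjusted p = 4.2e-13).

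Further shared rises were found for Fn3krp, a kinase that acts on sugar-modified proteins (2.84 ± 0.10, adjusted p = 1.7e-11), Tmem87a (2.12 ± 0.08) and Cap1, an actin regulator (1.18 ± 0.05, adjusted p = 3.8e-10). H2-Bl, of the MHC class I family (adjusted p = 6.5e-09), and Ttc34 (adjusted p = 2.1e-11) rose too, each detected on 9 knockout arrays and 1 wild-type array. Bricd5 was at least 3.33-fold higher and the chemokine receptor gene Ccr6 at least 2.19-fold higher, each detected on 0 wild-type arrays. The other tested probe of Ccr6 passed in the average and not in cortex, hippocampus or hypothalamus, and that of Masp2 passed in cortex and hippocampus and not in hypothalamus. Zbtb8os fell (adjusted p = 4.8e-08) and was detected on 9 wild-type arrays and 1 knockout array, and the apolipoprotein gene Apoa2 was detected on 3 wild-type arrays, those of hypothalamus, and on 0 knockout arrays. Cfap69, a protein of sperm and olfactory cilia, averaged -2.52 ± 0.41 (adjusted p = 9.2e-04) and was detected on 4 of 9 knockout arrays. Its adjusted p was 0.0758 when the arrays of a number were averaged first, a check chosen after the data were seen.

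Averaged over the regions, 932 probes passed the threshold, 458 higher and 474 lower in knockout. Of 589 probes called in any region, 101 were called in all 3, with 46 higher and 55 lower and 0 in opposite directions. Cortex and hippocampus shared 125 calls, cortex and hypothalamus 126, and hippocampus and hypothalamus 119, where lists independent of each other would share 5.23, 6.66 and 3.10. The 125, 126 and 119 shared calls had the same direction in both regions. Averaging the 3 arrays of a number into 1 value first, which tests 3 against 3 values, gave 343 probes.

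**Figure D1:**
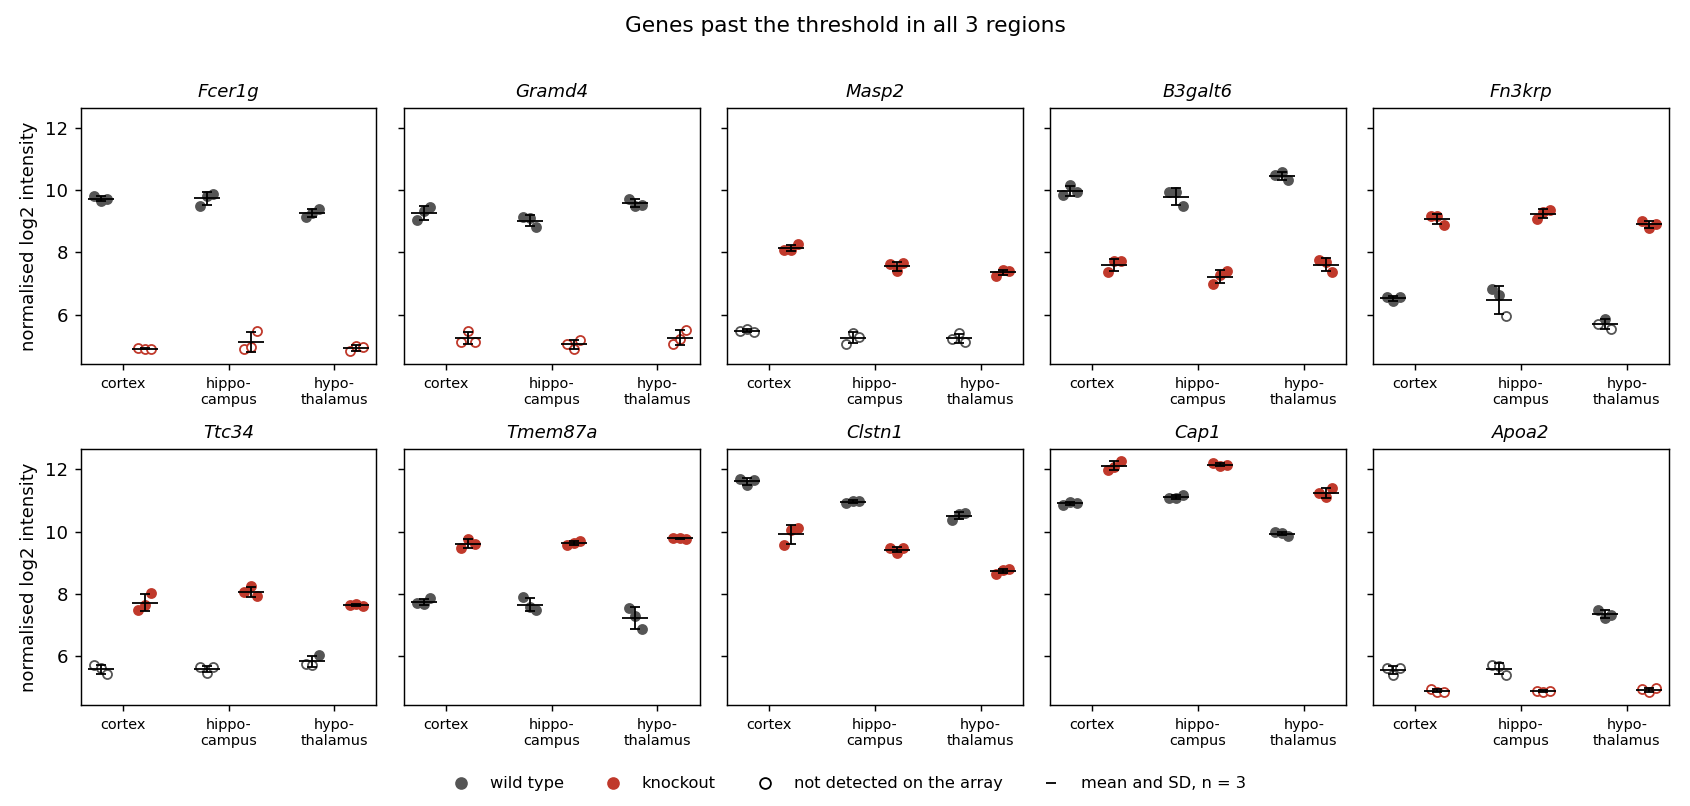
Normalised log2 intensity (vertical axis) of the 10 named genes past the threshold in all 3 regions, for the wild-type and knockout arrays of each region; points are arrays, open points are arrays on which the probe was not detected, and bars give the mean and SD (n = 3). Fcer1g and Gramd4 were detected on 9 wild-type and 0 knockout arrays, while Masp2 was detected on 9 knockout and 0 wild-type arrays.

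The changed genes were not spread evenly over the chromosomes. This count was made after the data were seen, with 1 probe per gene for 10508 genes placed by the RefSeq order. On chromosome 4, which carries Tas1r3, 113 of 637 genes had changed in the average over regions (17.7%, 52 higher and 61 lower), against 6.24% of all genes (Fisher's exact test, two-sided, adjusted p = 3.3e-24 over the chromosomes). On chromosome 17 it was 68 of 502 (13.5%, adjusted p = 9.9e-09), and on chromosome 5 it was 56 of 663 (8.45%, adjusted p = 0.0497). The share was below that of all genes, with adjusted p from 0.00359 to 0.0499, on chromosomes 7, 10, 11, 12, 14 and X. Each chromosome was compared with all the others, so the high shares on chromosomes 4 and 17 entered these comparisons. The test also takes neighbouring genes as independent. Chromosome 4 also held 28 of the 71 genes changed in all 3 regions, among them B3galt6, Clstn1, Masp2, Ttc34 and Cap1. Fcer1g and Apoa2 lie together on chromosome 1, where 16 of the 20 consecutive measured genes from Fcgr3 to Copa had changed, 5 higher and 11 lower. Bricd5 lies in a run of 20 genes on chromosome 17, from Abca3 to Ndufb10, in which 10 had changed, and Tmem87a in one on chromosome 2, from Exd1 to Haus2, in which 9 had changed. H2-Bl and Ccr6, and Fpr2 and Fgd2 named below, also lie on chromosome 17.

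**Figure D2:**
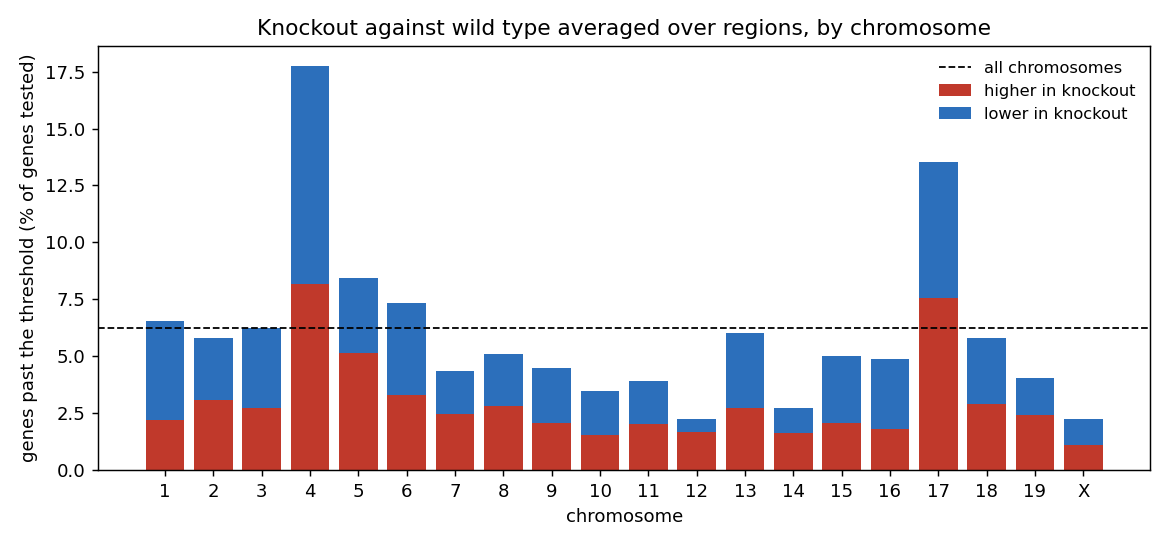
Share of tested genes past the threshold in the average over regions (vertical axis, percent) for each chromosome (horizontal axis), split into genes higher and lower in knockout; the dashed line marks 6.24%, the share over all chromosomes. Chromosomes 4 (17.7%) and 17 (13.5%) stand above the rest.

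A list of 109 genes near Tas1r3 on distal chromosome 4 had been fixed beforehand, and 70 were measured. In cortex 4 rose and 6 fell, in hippocampus 2 rose and 6 fell, and in hypothalamus 3 rose and 7 fell. Adjusted over the list alone, 12, 11 and 11 passed. B3galt6, Clstn1 and Klhl21 fell and Masp2 rose in each region; Klhl21, an adaptor of a ubiquitin ligase, fell by 0.89 ± 0.11 in cortex, 0.77 ± 0.11 in hippocampus and 0.89 ± 0.11 in hypothalamus. As a shift to one side the list passed camera in hippocampus (adjusted p = 0.0244), with adjusted p = 0.641 with an estimated correlation, and not in cortex (adjusted p = 0.119) or hypothalamus (adjusted p = 0.394). In cortex its median, 0.00369, and its mean, -0.06, differed in sign. Tested for change in either direction, fry's mixed test gave adjusted p = 3.5e-17, 5.2e-16 and 1.6e-16 in cortex, hippocampus and hypothalamus. The mixed test does not compare a list with the other genes, so a few strongly changed members can suffice. In cortex other lists passed it too, such as presynaptic genes (mixed test adjusted p = 8.8e-07), while taste signalling did not (0.110).

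In cortex the comparison asked which genes differ without T1R3 in the outer sheet of the forebrain. The largest falls were those of Fcer1g, at least 11.8-fold, and Gramd4, at least 8.64-fold. B3galt6 fell by 2.38 ± 0.16 (adjusted p = 2.4e-07) and Slc24a2, a sodium, calcium and potassium exchanger of neurons, fell by 2.10 ± 0.27 (adjusted p = 3.7e-04). The voltage-gated potassium channel gene Kcna1 fell by 1.74 ± 0.39 (adjusted p = 0.0275), and Kitl, the ligand of the KIT receptor, fell by 2.14 ± 0.48 (adjusted p = 0.0276), with knockout arrays spread by 1.24 and 1.59 (SD, n = 3). Masp2 was at least 4.14-fold higher, H2-Bl at least 3.63-fold and Ttc34 at least 3.09-fold.

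Sytl1, a vesicle trafficking gene, was at least 2.99-fold higher in cortex, Bricd5 at least 2.49-fold, Ccr6 at least 2.27-fold and Fpr2, a formyl peptide receptor of innate immune cells, at least 1.98-fold. Fn3krp rose by 2.54 ± 0.17, Tmem87a by 1.85 ± 0.14 and Stbd1, a glycogen-binding protein, by 1.66 ± 0.20. Uap1, which makes UDP-N-acetylglucosamine, fell by 1.74 ± 0.15, the cyclin gene Ccng2 fell by 1.88 ± 0.44 and Trim33 fell by 1.75 ± 0.36. None of the 3 other tested probes of Trim33 passed in the same direction, a count of 0. Zbtb8os was at least 2.70-fold lower.

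In total 417 probes passed in cortex, 178 higher and 239 lower. Over all probes tested in cortex, called or not, 16.9% had no overlap between the genotypes, which chance gives for 10%. The count of 417 moved with single arrays: it was 660 without knockout array 1, 191 without knockout array 3, 172 without wild-type array 1 and 159 without wild-type array 3. It was 63 when only the 6 cortex arrays entered the fit, and 266 without the 3 arrays that carried striatal and hypothalamic markers, an alternative added after the data were seen that leaves 1 knockout array, assumed to vary like the other groups.

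Among the lists, genes of myelin and oligodendrocytes were lower in knockout cortex: 3 of 25 fell, 21 of 25 had a negative change, and 8 passed adjusted over the list alone. Mog, a myelin surface protein, fell by 0.76 ± 0.16, the tetraspanin gene Tspan2 by 0.59 ± 0.13 and the tight junction gene Cldn11 by 0.53 ± 0.13. The list passed camera (adjusted p = 2.2e-07), with adjusted p = 0.195 with an estimated correlation. Interferon response genes were lower as a list (0 of 23 past the threshold, 3 adjusted over the list alone, camera adjusted p = 0.00114), with adjusted p = 0.447 with an estimated correlation. Circadian clock genes were lower (adjusted p = 0.00774), with adjusted p = 0.465 with an estimated correlation. Of the 18 measured, Per3 was detected on 3 wild-type and 0 knockout arrays (adjusted p = 9.3e-04) and Rorb fell by 0.73 ± 0.13, 2 also when adjusted over the list alone. Per3 is one of the distal chromosome 4 neighbours of Tas1r3.

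Oxidative phosphorylation genes were higher in knockout cortex, with 60 of 68 above wild type (camera adjusted p = 4.1e-04), and adjusted p = 0.483 with an estimated correlation. Ndufb10, a subunit of respiratory complex I, rose by 1.07 ± 0.19 and Sdhc, of complex II, by 0.52 ± 0.11, 2 also when adjusted over the list alone. Both lie in the changed runs on chromosomes 17 and 1. Cytosolic ribosomal proteins were higher for 47 of 53 genes (camera adjusted p = 8.6e-04), with adjusted p = 0.522 with an estimated correlation. The 1 member past the threshold, Rps15a, fell by 1.03 ± 0.10, and 1 passed adjusted over the list alone. By camera, 10 of 741 Reactome pathways were higher, named for translation, nonsense-mediated decay, protein targeting and respiratory electron transport. The 10 include translation elongation (median 0.12 over 56 genes, adjusted p = 0.0296) and respiratory electron transport (median 0.09 over 59 genes, adjusted p = 0.0432). With an estimated correlation 0 pathways passed, these 2 having adjusted p = 0.752 and adjusted p = 0.767. The pathway count was 0 without knockout array 1, without knockout array 2, without wild-type array 2, with the deposited z scores and with only the 6 cortex arrays in the fit.

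Markers of neighbouring tissue also differed among the cortex arrays. Striatum markers were higher as a list (20 of 21 genes above wild type, 0 past the threshold and 0 adjusted over the list alone, camera adjusted p = 0.0122), with adjusted p = 0.612 with an estimated correlation. Their mean stood at 1.19 on knockout array 1, 0.64 on knockout array 3 and 0.51 on wild-type array 2, but at -0.51 on knockout array 2, relative to the wild-type mean. Hypothalamus markers were higher too (0 of 28 past the threshold and 0 adjusted over the list alone, camera adjusted p = 0.00114), with adjusted p = 0.522 with an estimated correlation. Their mean was 0.97 on knockout array 1. Together 7 of 32 lists passed camera in cortex, 0 with an estimated correlation and 2 with fry, and the remaining 25 had adjusted p-values from 0.0730 to 0.988. The count of lists was 3 without knockout array 1 and 11 without knockout array 2.

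In hippocampus, a region of learning and memory, Fcer1g was at least 13.2-fold and Gramd4 at least 8.02-fold lower in knockout. B3galt6 fell by 2.57 ± 0.16 (adjusted p = 7.5e-08), Clstn1 by 1.54 ± 0.12 (adjusted p = 2.2e-06) and Uap1 by 1.41 ± 0.15. Fn3krp rose by 2.77 ± 0.17 (adjusted p = 8.3e-08), Tmem87a by 1.97 ± 0.14 and Stbd1 by 1.94 ± 0.20. Ttc34 was at least 4.34-fold higher, Bricd5 at least 3.57-fold and Masp2 at least 3.04-fold. Ccr6, H2-Bl and Fpr2 were at least 2.44-fold, 1.64-fold and 1.60-fold higher.

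Fgd2, a regulator of the actin cytoskeleton in antigen-presenting cells, rose by 1.61 ± 0.23 in hippocampus. Zbtb8os fell by 2.02 ± 0.24 and Pex19, needed for peroxisome assembly, fell by 1.23 ± 0.14, with its other tested probe called in the same direction. The clock gene Per3 was at least 1.94-fold lower, Eya3 at least 1.93-fold and Rplp0 at least 1.23-fold. The other tested probe of Eya3 and that of Rplp0 were not called. Sv2a, a synaptic vesicle protein, fell by 0.42 ± 0.08, Tsc2, which restrains mTOR signalling and lies in the changed run on chromosome 17, fell by 0.80 ± 0.14 at 1 of its 2 tested probes, and Ntsr1, a neurotensin receptor, fell by 0.58 ± 0.13. Chrnb2, a nicotinic receptor subunit, rose by 0.34 ± 0.07.

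In hippocampus 194 probes passed, 105 higher and 89 lower. Over all probes tested in hippocampus, 15.5% had no overlap between the genotypes, which chance gives for 10%. With only the 6 hippocampus arrays in the fit the count of 194 was 94. Besides the distal chromosome 4 neighbours, 2 lists passed camera. Interferon response genes were lower (0 of 23 past the threshold, 6 adjusted over the list alone, camera adjusted p = 0.0406), with adjusted p = 0.641 with an estimated correlation. Microglia genes were lower (camera adjusted p = 0.0408), with adjusted p = 0.641 with an estimated correlation. Of 22 measured, Fcer1g fell and Fcgr3, which encodes an Fc receptor that pairs with it and neighbours it on chromosome 1, rose by 1.17 ± 0.15; 3 passed adjusted over the list alone. Without Fcer1g, left out after the data were seen, the mean of the microglia list was -0.07 in place of -0.28 and its adjusted p was 0.259. Without the changed genes that have a changed neighbour, also left out after the data were seen, the interferon and microglia lists had adjusted p = 0.164 and 0.164 and the distal chromosome 4 list 0.195, so that 0 lists passed.

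Of 32 lists, 3 passed camera in hippocampus, 0 with an estimated correlation and 0 with fry, and the other 29 had adjusted p-values from 0.0699 to 0.983. The count of lists was 0 without knockout array 1 and 5 without wild-type array 2. By camera, 0 of 741 Reactome pathways passed; 31 had an unadjusted p under 0.05, and 0 passed with an estimated correlation. The choroid plexus list differed among the wild-type arrays, at -1.89 on array 1 and 0.94 on arrays 2 and 3 relative to their mean.

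In hypothalamus, the region that governs feeding and hormone release, Prl, the pituitary hormone prolactin, was at least 12.1-fold lower in knockout (adjusted p = 2.9e-06). Cga, the alpha subunit of the pituitary glycoprotein hormones, fell by 2.76 ± 0.58 (adjusted p = 0.0216). Fcer1g was at least 10.5-fold, Gramd4 at least 13.1-fold and Apoa2 at least 2.79-fold lower. The neuropeptide gene Npvf rose by 1.63 ± 0.25 (adjusted p = 0.00177), and Nmu and Vip rose by 0.56 ± 0.12 and 0.55 ± 0.13.

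H2-Bl rose by 3.69 ± 0.26 in hypothalamus (adjusted p = 2.9e-07), Fn3krp by 3.19 ± 0.17, Tmem87a by 2.54 ± 0.14, Fpr2 by 2.18 ± 0.20 and Ttc34 by 1.81 ± 0.13. Bricd5 was at least 4.17-fold higher, Padi2, a peptidylarginine deiminase found in oligodendrocytes, at least 3.84-fold, Masp2 at least 2.93-fold, Golm2 at least 2.92-fold and Ccr6 at least 1.91-fold. B3galt6 fell by 2.85 ± 0.16 and Ccng2 fell by 2.06 ± 0.44, and Zbtb8os was at least 4.32-fold lower. Ogn, a proteoglycan of connective tissue, fell by 2.10 ± 0.43 and Itih2, which binds hyaluronan, fell too (adjusted p = 0.0241). None of the 2 other tested probes of Ogn passed, a count of 0.

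In total 247 probes passed in hypothalamus, 105 higher and 142 lower. Over all probes tested in hypothalamus, 19.1% had no overlap between the genotypes, which chance gives for 10%. The count of 247 was 618 with array quality weights, 164 without knockout array 3, 151 without wild-type array 2 and 147 without wild-type array 3.

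The meningeal list had 19 of 19 measured genes lower in knockout hypothalamus, 5 of them past the threshold and 18 adjusted over the list alone. Lum, a matrix proteoglycan, fell by 1.43 ± 0.18, Mgp, matrix Gla protein, fell by 1.65 ± 0.33, Ptgds, prostaglandin D synthase, fell by 1.46 ± 0.30 and the connexin gene Gjb2 by 1.13 ± 0.20. The list passed camera (adjusted p = 1.7e-21), with adjusted p = 0.0853 with an estimated correlation. Its mean lay between -1.25 and -1.12 on the knockout arrays, and at -0.75, -0.05 and 0.80 on wild-type arrays 1, 2 and 3. Of 7 pituitary genes 4 were lower, Prl, Cga, Gh and Tshb, and 3 higher, Chgb, Gal and Pomc. Gal and Pomc also served as hypothalamus markers and were highest there in wild type. Tshb lay 0.91 above the wild-type mean on knockout array 2. Prl and Cga passed the threshold, and 3 genes passed adjusted over the list alone. The pituitary list passed camera (adjusted p = 0.00231), with adjusted p = 0.0853 with an estimated correlation. The pituitary list averaged -1.66, -0.99 and -2.09 on knockout arrays 1, 2 and 3.

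Glial and immune lists were also lower in knockout hypothalamus. Myelin and oligodendrocyte genes were lower for 24 of 25 (0 past the threshold, 5 adjusted over the list alone, camera adjusted p = 2.2e-07), with adjusted p = 0.0853 with an estimated correlation. Interferon response genes were lower for 21 of 23 (camera adjusted p = 4.4e-06), with adjusted p = 0.0919 with an estimated correlation; Oasl2 fell by 1.31 ± 0.17 and 5 passed adjusted over the list alone. Microglia genes were lower for 18 of 22 (7 adjusted over the list alone, camera adjusted p = 5.6e-05), with adjusted p = 0.175 with an estimated correlation. Fcer1g fell and Fcgr3 rose by 1.01 ± 0.15, and without Fcer1g the list had a mean of -0.20 and adjusted p = 0.00457.

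Hypothalamic neuropeptides were higher for 22 of 27 genes, 3 of them past the threshold and 4 adjusted over the list alone (camera adjusted p = 0.00502), with adjusted p = 0.175 with an estimated correlation. Oligodendrocyte precursor genes (3 of 9 adjusted over the list alone, camera adjusted p = 0.0215) and astrocyte genes (0 of 25, camera adjusted p = 0.0379) were lower. These had adjusted p = 0.0919 and adjusted p = 0.220 with an estimated correlation. Without the changed genes that have a changed neighbour, left out after the data were seen, the precursor list had adjusted p = 0.0989 and the red blood cell list 0.0549, and 7 lists passed in place of 9. Red blood cell genes were lower for 4 of 5 (4 adjusted over the list alone, camera adjusted p = 0.0488), with adjusted p = 0.259 with an estimated correlation. The globin gene Hbb-bt was at -1.14 ± 0.29 (adjusted p = 0.0678). Another globin gene, Hbb-b2, chosen after its values were seen, went the other way on knockout arrays 1 and 3. It stood at 8.07, 5.27 and 8.33 on knockout arrays 1, 2 and 3, against 5.22, 5.22 and 5.17 on the wild-type arrays. The same numbers were high in knockout cortex (7.98, 5.66 and 9.01) and hippocampus (8.33, 5.67 and 8.60). Hbb-b2 thus followed the number of the knockout array in each region and was not particular to hypothalamus. Together 9 of 32 lists passed camera, 0 with an estimated correlation and 9 with fry, and the remaining 23 had adjusted p-values from 0.0611 to 0.981. The lists differ between the tools: astrocytes (fry adjusted p = 0.118) and red blood cells (0.0943) did not pass fry, while taste signalling (0.00902) and presynaptic genes (0.00902) did. The taste signalling list includes Gnb1, which lies near Tas1r3 on distal chromosome 4. By camera 0 of 741 Reactome pathways passed; 67 had an unadjusted p under 0.05, 0 passed with an estimated correlation, and 9 passed without wild-type array 1.

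**Figure D3:**
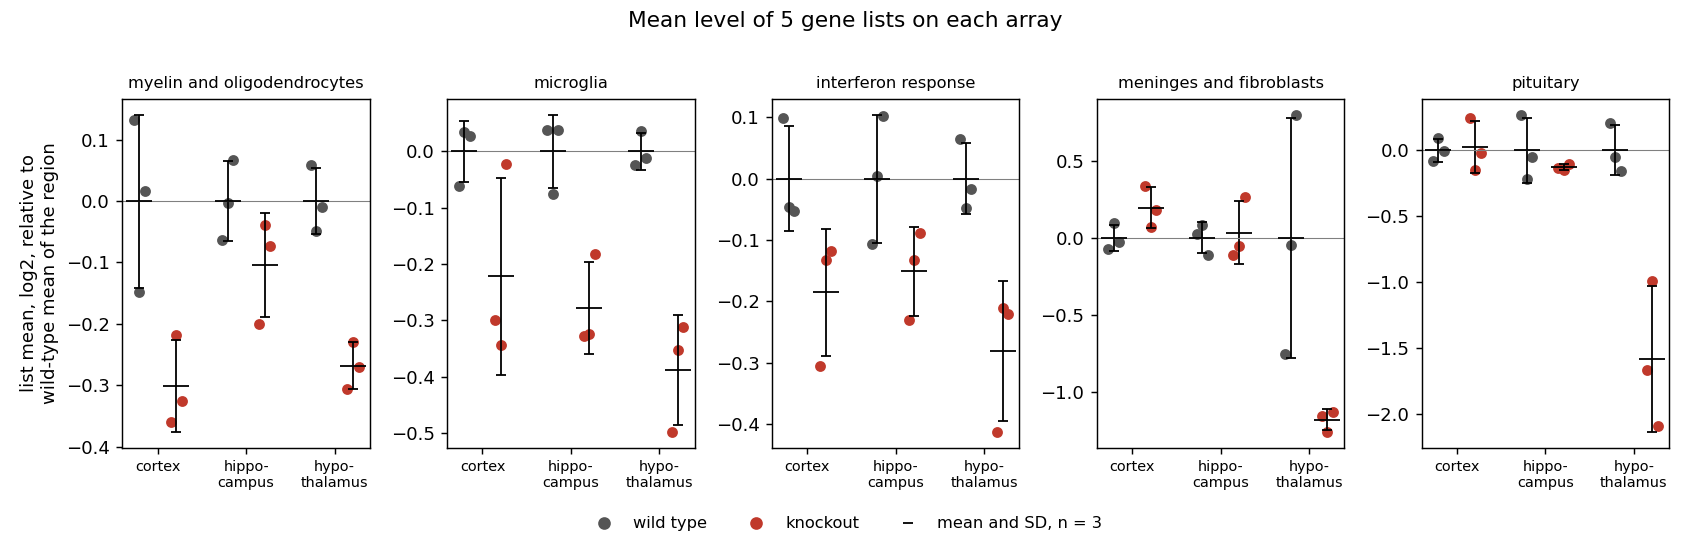
Mean log2 level of 5 gene lists on each array relative to the wild-type mean of the region (vertical axis, with its own scale in each panel), for the wild-type and knockout arrays of each region; points are arrays and bars the mean and SD (n = 3). In hypothalamus the meningeal list lay between -1.25 and -1.12 on the knockout arrays and between -0.75 and 0.80 on the wild-type arrays.

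Whether the knockout effect differed between the regions was tested directly. Prl was at least 12.1-fold lower in knockout hypothalamus, while in cortex and hippocampus it was not detected on any array of either genotype (adjusted p = 0.00268 for the difference). Stbd1 was at 1.66 in cortex, 1.94 in hippocampus and 0.09 in hypothalamus (adjusted p = 0.0425). Lum was at -0.02, 0.22 and -1.43 (adjusted p = 0.0425). Padi6, a relative of Padi2, was detected in wild-type cortex and in no other group, at least 1.17-fold lower in knockout cortex (adjusted p = 4.4e-05 for the difference between regions). Apoa2 was detected in wild-type hypothalamus and in no other group (adjusted p = 1.8e-05).

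The test between regions called 7 of 15476 probes, the others being Mrc1, a macrophage receptor with changes of 0.07, 0.17 and -1.04 in cortex, hippocampus and hypothalamus, and 1 unnamed probe. Mrc1 lies outside the naming rule and was chosen after its value was seen. The count was 129 without the cortex knockout array 1, 26 without the hypothalamus wild-type array 1 and 13 without the hypothalamus knockout array 2 or the cortex wild-type array 2. It was 8 without the cortex knockout array 2, 5 without the hippocampus wild-type array 2, and 3 or 4 without each of the remaining 12 arrays.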

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

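Among the tests weighed here, those of gene positions and genes that rose, of the chromosome segments, of the shared animal, of shared processing, and of the pituitary and meningeal genes were chosen only after the result was seen, as were the animal averages.

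The test between regions, a difference between groups under the same contrast, called 7 probes: Apoa2 (adjusted p = 1.8e-05), Padi6 (4.4e-05), Prl (0.00268), Stbd1 (0.0425), Lum (0.0425), Mrc1 (0.0425) and 1 unnamed probe (0.0425). Prl, Lum and Mrc1 were lower in knockout hypothalamus, and Stbd1 was higher in knockout cortex and hippocampus. Apoa2, Padi6 and Prl were each detected in 1 region only, so a fall of like size could not show in the others. Of 100 splits of the arrays within regions, the real one included, 7 called as many probes as the real split, with 174 as the highest of the others. Chance is not excluded for the count of 7. The splits were drawn in each region on its own, with the genotypes reversed at random. They can turn a knockout effect shared by the regions into a difference between them, so they cannot decide on chance here. Without the cortex knockout array 1, which carried the most striatal and hypothalamic marker signal, the real count was 129. It was 26 without the hypothalamus wild-type array 1, 13 without the hypothalamus knockout array 2 or the cortex wild-type array 2, and 3 or 4 without each of 12 others.

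The first pattern weighed is that changed genes lie next to one another: in the average over regions 113 pairs of neighbouring measured genes had both changed, against a mean of 40.7 and a highest value of 65 in 10000 shuffles (permutation test, p = 1.0e-04, the smallest possible). The ratio to the shuffled mean was 2.78, and 1.45 for genes differing between wild-type cortex and hippocampus. A response that takes no account of position is therefore unlikely to account for all the changes. Of the 656 changed genes, 193 had a changed neighbour, and for the others the test does not decide. Base differences under the probes, which lower a signal, would leave few rises, yet 42.5% of the 193 changed genes with a changed neighbour rose (95% interval 35.4% to 49.8%); the 35 other probes of 28 fallen genes had a median of -0.28 (95% interval -0.33 to -0.17), 16 of them called in the same direction and 0 in the opposite one. For single genes such differences stay open: chosen after their values were seen, Taf6, Atp8a1 and Cdkn1b changed by -2.06, -1.09 and -0.72 at the called probe and by 0.05, -0.04 and 0.11 at the other, and Fcer1g, Gramd4, B3galt6 and Clstn1 had 0 other tested probes. Segments of another strain, left by the crossing of the line, could place changes of expression around neighbouring genes. Segments still varying within the line would set single knockout animals apart. Of 4 neighbouring pairs among 34 genes varying by array number, 100% set the same number apart (shuffled mean 37.1%, highest 100%, permutation test p = 0.0177). With 4 pairs this stays a hypothesis. Segments shared by all knockout animals would set none apart. The test therefore does not reach genes changed on every knockout array, such as Fcer1g and Masp2.

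The second is that some probes deviate together on knockout arrays of the same number: 50 probes differed by number over the 3 regions, against at most 7 for the other 35 of 36 relabellings (exact p = 0.0278), consistent with the 3 arrays of a number coming from the same animal, although the labels give 18 animals. Over all probes the residuals of knockout arrays 1, 2 and 3 correlated by -0.15, 0.30 and -0.07 between cortex and hippocampus, where a pair of different numbers reached 0.32, by 0.08, 0.24 and 0.23 between cortex and hypothalamus and by 0.22, 0.26 and 0.37 between hippocampus and hypothalamus. In wild type the count of probes that differed by number was 0 by limma (973 at an unadjusted p under 0.05, against 1477 in knockout), which gives no sign that arrays of a number were processed together, but residuals of wild-type arrays 1, 2 and 3 correlated by 0.16, 0.07 and 0.18 between hippocampus and hypothalamus, against 0.01, 0.12 and -0.03 between cortex and hippocampus and -0.07, 0.07 and -0.02 between cortex and hypothalamus, so this stays open. Among knockout arrays Cfap69 was highest on number 1 in each region, with a spread of 2.50 between knockout numbers, and Mak16 (3.42), Hbb-b2 (3.11), Usp25 (2.38) and Taf6 (2.30), chosen after their values were seen, also differed by number. Averaging the arrays of a number first gave 343 probes for the average over regions, against 932 with each array on its own.

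The third is that the pituitary hormone genes Prl and Cga and the meningeal genes were lower in knockout hypothalamus. Less attached tissue in the knockout dissections may account for the meningeal genes: the list mean ranged over 1.55 among the 3 wild-type arrays, more than the -1.18 by which the knockout mean lay from wild type, and over 0.13 among the knockout arrays. For the pituitary the test did not decide. Prl and Tshb parted by 5.16 within knockout array 2, more than the bound of 2 first written for a cause other than dissection, but Prl and Gh parted nearly as far, by 4.43, within wild-type array 2, and Gh had an SD of 2.81 in wild type. A regulation of prolactin by T1R3 is therefore neither shown nor ruled out.

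Other splits of the arrays were run for each count but the 0 Reactome pathways in hippocampus and in hypothalamus (31 and 67 at an unadjusted p under 0.05 by camera). For the average over regions, 1 of 100 splits, the real one, called as many as 932 probes (highest other 14), and for the wild-type regions 1 of 100 called as many as 8466 (highest other 6049), so chance is excluded for both where each array counts as its own animal. If the 3 arrays of a number come from the same animal, 10 splits of the animals remain for the average over regions, too few for a share under 0.05; these were not run. With 3 against 3 arrays the 10 splits are too few for a share under 0.05: probes in cortex 417 in the real split (highest other 177, 1 split as large), in hippocampus 194 (highest other 0, 1 split) and in hypothalamus 247 (highest other 3, 1 split). For lists the real counts were 7 in cortex (highest other 11, 4 splits as large), 3 in hippocampus (5, 7 splits) and 9 in hypothalamus (9, 2 splits), and for Reactome pathways in cortex 10 (2, 1 split).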

How the results depend on the processing

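The animal averages, the animal as a fixed block, the arrays of doubted dissection left out, the genes with changed neighbours left out and the microglia list without Fcer1g were chosen only after the result was seen. Of 1450 values of named genes under the alternatives, 1330 kept their direction and side of the threshold. A further 120 kept their direction without passing, and 0 reversed. Leaving out single arrays gave 913, 173 and 0 of 1086. Part of this was fixed in advance. The genes were picked for passing in the same data. At a threshold of 0.10 the fit is the same, so its 141 values could not change. Values of the test between regions have no direction and could not reverse. Of the 120, 45 arose with only the 6 arrays of a region in the fit, which have fewer degrees of freedom. Signal over background limits the folds of Fcer1g, Gramd4 and Prl to bounds and leaves Tas1r3 unmeasured. A block for the slide was not run, as no slide is given.

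Values moved by over 1.5 times as follows; where the setting does not itself use fewer arrays, genes or a different threshold, the cause was not tested. With the deposited z scores, 4 probes differed between regions, 0 Reactome pathways passed in cortex and 5 lists in hippocampus. With no filter on detection these were 3, 17 and 1, with 1 pathway in hypothalamus; with detection on all 18 arrays, 3 probes and 1 list in hippocampus. With only the 6 arrays of a region, 63 probes passed in cortex and 94 in hippocampus, 0 pathways in cortex and 5 lists in hippocampus. The replicate block gave 259 probes in cortex, 3 between regions and 5 lists in hippocampus; residuals of knockout and wild-type arrays of a number correlated by -0.08, -0.28 and 0.06 in cortex, 0.07, 0.12 and 0.08 in hippocampus and 0.13, 0.06 and 0.22 in hypothalamus, positive in the last pair of regions but not over 0.1 for every number. Array weights gave 618 probes in hypothalamus, 14 between regions and 0 lists in hippocampus. At a threshold of 0.10, 684 probes passed in cortex and 292 in hippocampus. With an estimated correlation 0 lists passed in cortex, hippocampus and hypothalamus and 0 pathways in cortex, and fry passed 2 lists in cortex and 0 in hippocampus. Animal averages gave 343 probes for the average over regions. Without the doubted arrays, 266 probes and 0 pathways passed in cortex and 9 pathways in hypothalamus. Leaving out the doubted arrays gave 175 probes in hippocampus and 229 in hypothalamus, the counts found without wild-type array 1 of each region. In hypothalamus that array had the lowest meningeal list mean of the wild-type arrays, and the array with the highest stayed in. The setting therefore cannot decide whether attached tissue accounts for the meningeal genes. Without genes in changed neighbourhoods 0 lists passed in hippocampus.

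Leaving out 1 array at a time, where a group of 2 remains, gave 159 to 660 probes in cortex (660 without knockout array 1, 191 without knockout array 3, 172 and 159 without wild-type arrays 1 and 3), 130 to 175 in hippocampus and 147 to 229 in hypothalamus (164 without knockout array 3, 151 and 147 without wild-type arrays 2 and 3). The average over regions ranged from 688 to 1095, the wild-type regions from 7436 to 8346 and the test between regions from 3 to 129 (129 without the cortex knockout array 1, 26 without the hypothalamus wild-type array 1). Lists ranged from 3 (without knockout array 1) to 11 (without knockout array 2) in cortex, 0 (without knockout array 1) to 5 (without wild-type array 2) in hippocampus and 7 to 9 in hypothalamus. Reactome pathways ranged from 0 (without knockout array 1, knockout array 2 or wild-type array 2) to 10 in cortex, 0 to 0 in hippocampus and 0 to 9 (without wild-type array 1) in hypothalamus.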

Other observations

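The glucocorticoid response list, singled out only after the result was seen and not tested by number, ran downward with the number of the knockout arrays. Relative to the wild-type mean of the region, knockout arrays 1, 2 and 3 lay at 0.13, 0.00 and -0.38 in cortex, 0.37, 0.03 and -0.31 in hippocampus, and 0.31, -0.05 and -0.43 in hypothalamus. The list did not pass camera in cortex, hippocampus or hypothalamus (adjusted p = 0.235, 0.928 and 0.394).

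Single genes of lists that did not pass as a whole were also past the threshold. Rgs5, a marker of pericytes, rose in cortex (1.17 ± 0.16, adjusted p = 7.3e-04), hippocampus (0.95 ± 0.16, adjusted p = 0.00557) and hypothalamus (1.08 ± 0.16, adjusted p = 0.00146). In cortex Hcrtr1, an orexin receptor, rose by 0.54 ± 0.10, Dlx2, a transcription factor of interneurons, by 0.54 ± 0.12 and Syngr3, a synaptic vesicle protein, by 0.41 ± 0.07, while Trem2, a microglial receptor, fell by 0.57 ± 0.15 and Prkaa2, a catalytic subunit of AMP kinase, fell by 1.07 ± 0.27. Syngr3 lies in the changed run on chromosome 17. Rps15a fell in hippocampus by 1.14 ± 0.10 and in hypothalamus by 1.63 ± 0.10. Tnnt1, a thalamus marker, rose by 1.00 ± 0.19 in hippocampus and 0.94 ± 0.19 in hypothalamus.

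A list of genes known to differ between C57BL/6J and other strains, with 4 of 7 measured, had 0 genes past the threshold in limma and 0 adjusted over the list alone, and camera adjusted p = 0.571, 0.928 and 0.434 in cortex, hippocampus and hypothalamus. With 4 genes the list cannot decide on segments of another strain elsewhere on the chromosomes.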
